A study of Homo sapiens with 6 samples.

How the data were processed

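HN30 cells were grown in culture and carried short hairpin RNA against KMT2D or a non-targeting hairpin, with 3 libraries per group. Per the labels' protocols, RNA was taken with a column kit, directional libraries were made and paired reads of 76 bp were sequenced. The labels do not say which of several KMT2D hairpins each library carried, or whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

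The deposited values were raw read counts per gene symbol, 1 column per library. The submitters' processing notes name STAR 2.7.2b, FastQC 0.11.8, featureCounts, Subread 1.6.3, DESeq2 and the genome build hg19, without stating the role of each. The annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes with near-identical copies, overlapping genes and antisense genes can therefore share counts. All 6 value columns were matched to samples by name and 0 were left unmatched. The table held 26364 symbols, of which 6770 had no count in any library, and 23035 were found among current or older gene symbols. It held 0 mitochondrially encoded genes. Only gene-level counts were used, since the series states that reads are withheld for reasons of consent.

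Counts were analysed in R 4.3.3 with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0. Genes were kept by edgeR's filterByExpr with its minimum count of 10 and minimum total of 15, which left 13590. Libraries were scaled with TMM factors, and CPM values are on that scale unless said otherwise. Library totals lay between 17738360 and 21199192 counts, so 3 counts correspond to 0.142 to 0.169 CPM in a library before TMM scaling. Such floors cover counting error only. Log2 CPM used a prior count of 2. The test was edgeR's quasi-likelihood F test (robust, two-sided) of shKMT2D against shNT, adjusted by the Benjamini-Hochberg method over all tested genes, with a threshold of 0.05. Standard errors were taken from the fold change and the F statistic. These settings were fixed before the data were examined.

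Before the data were examined, 33 gene lists were also fixed, covering 1166 genes, of which 1105 were in the table. Lists with at least 5 tested members, 31 in all, were tested with camera at a preset correlation of 0.01 between genes, adjusted over the lists. The list of mitochondrially encoded genes had 0 members and that of melanocyte and neuroendocrine markers had 4 tested members, too few for a test. Because camera's preset correlation can be too low, each list was also tested with an estimated correlation and with fry. The named genes were fixed by rule: KMT2D, then called genes with non-overlapping groups and a mean of at least 5 CPM in the higher group, then for each tested list up to 3 called members, or members of smallest p until 2 were named. As no gene was called, the second part named 0 genes. Some genes that the rule or a count covers are not reported here by name. Genes outside this rule are said to be named after their values were seen.

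Libraries of equal replicate number deviated together. The correlation across genes of their deviations from the group means was 0.504, 0.66 and 0.585 for replicates 1, 2 and 3, each above the limit of 0.1 and each the highest for that library among libraries of the other group. Also above 0.1 were shNT replicate 1 with shKMT2D replicate 3 (0.346) and shNT replicate 3 with shKMT2D replicate 1 (0.239). The limit alone therefore does not part equal from unequal numbers. The difference between replicates 1 and 3 correlated across genes between the groups as well (r = 0.345). The numbers were therefore taken to pair the samples, from the data and the labels' numbering, and fits with the replicate number as a block are given where they change a call. Genes are not independent replicates, so these correlations describe the libraries only. No 2 libraries agreed within sampling noise: the chi-square statistic per degree of freedom was at least 13.0 for every pair of libraries.

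The share of counts in the 10 highest genes was 4.99 ± 1.06% in shNT and 5.48 ± 1.38% in shKMT2D (SD, n = 3 each; exact permutation p = 0.6, adjusted p = 0.875 over the measures compared, which were total counts, genes detected and the shares in the highest, ribosomal protein and histone genes). The share in ribosomal protein genes was 6.37 ± 0.739% and 7.13 ± 1.73% (exact permutation p = 0.6, adjusted p = 0.875). With 3 libraries against 3 the smallest two-sided p is 0.1.

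The fits were tested on simulated counts drawn from the real genes' means and library sizes, with 100 genes changed 2-fold and 100 changed 4-fold, over 13590 genes. Without a shared replicate effect, edgeR recovered 17% of 2-fold and 76% of 4-fold changes with 6 false calls among 100, and DESeq2 45% and 92% with 50 false calls among 192. With the block in these counts, edgeR recovered 15% and 76% with 13 false calls among 107, and DESeq2 44% and 89% with 71 false calls among 211. With a shared replicate effect, equal in both groups, edgeR recovered 0% and 33% without the block and 74% and 93% with it. Its false calls were 0 among 33 without the block and 13 among 186 with it. DESeq2 recovered 28% and 82% without the block and 73% and 91% with it, with 0 false calls among 111 and 14 among 185. A list shifted by -0.5 was recovered by camera with the preset correlation in each simulation and 0 of 30 other lists were called. Simulated genes varied independently, whereas the estimated correlation within the real lists reached 0.966 (mitosis genes). The 0 therefore does not bear on the real list calls. Neither camera with an estimated correlation nor fry was run on the simulated counts, so their power to recover such a shift is not known.

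The alternatives were DESeq2, limma-voom, RLE and upper-quartile factors, library sizes alone, no filter on low counts, a filter of CPM of at least 1 in at least 3 libraries, glmTreat against a 1.5-fold change, an adjusted p below 0.01, the replicate block, and leaving out each library. Alternatives with the block in DESeq2 and limma-voom, with both replicate-2 libraries left out, with library weights, and DESeq2 without each library were chosen after seeing the data. GC content and transcript length were taken from GENCODE release 29 by symbol, with no coordinates, since that annotation belongs to another genome build.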

Results

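The data were RNA sequencing counts per gene from HN30, an established cell line of head and neck squamous cell carcinoma. Of the 6 libraries, 3 came from cells with short hairpin RNA against KMT2D (shKMT2D, replicates 1 to 3) and 3 came from cells with a non-targeting hairpin (shNT, replicates 1 to 3). KMT2D is a histone H3 lysine methyltransferase that acts mainly at enhancers. Total counts per library were 20276302, 17738360 and 20631078 in shNT replicates 1, 2 and 3, and 21199192, 19552078 and 18671433 in shKMT2D replicates 1, 2 and 3. Of 26364 gene symbols, 13590 were tested. The comparison asks which transcripts differ between cells with and without the hairpin against KMT2D.

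KMT2D itself, the target of the hairpin, was measured at 177, 107 and 149 CPM (counts relative to the TMM-scaled library total) in shNT replicates 1, 2 and 3, and at 118, 103 and 110 CPM in the shKMT2D libraries. The group means were 144 ± 35.4 CPM in shNT and 111 ± 7.32 CPM in shKMT2D (SD, n = 3 each), a log2 fold change of -0.39 ± 0.21 (SE). Without pairing, the difference did not exceed the spread between libraries: edgeR's quasi-likelihood test gave p = 0.109 (adjusted p = 1.00) and the exact two-sided permutation test of log2 CPM gave p = 0.3, where 3 against 3 libraries cannot go below 0.1. The lowest control library, shNT replicate 2, lay below shKMT2D replicates 1 and 3. Between libraries of equal replicate number the log2 differences were -0.59, -0.05 and -0.44 for replicates 1, 2 and 3, so all 3 had the same sign, and the exact sign-flip test gave p = 0.25, the smallest that 3 pairs allow. With the replicate block, edgeR gave a log2 fold change of -0.36 ± 0.14 (SE) with an unadjusted p of 0.0398, which did not pass over all genes (adjusted p = 0.564). Without shNT replicate 1 the log2 fold change was -0.21. The 18 tested members of the KMT2 methyltransferase complexes showed no call at the threshold over all genes or adjusted over the list alone, and the list did not pass camera (adjusted p = 0.225), although it was called lower without shNT replicate 2 (adjusted p = 0.00811). WDR5, a core subunit shared by these complexes, had a log2 fold change of -0.32 ± 0.24 (SE). Among 34 other chromatin regulators no gene was called either way and camera gave an adjusted p of 0.569. In that list KDM1A, a histone demethylase, measured 0.33 ± 0.17 and CBX2, a Polycomb subunit, 0.47 ± 0.32 (log2 fold change ± SE).

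**Figure D1:**
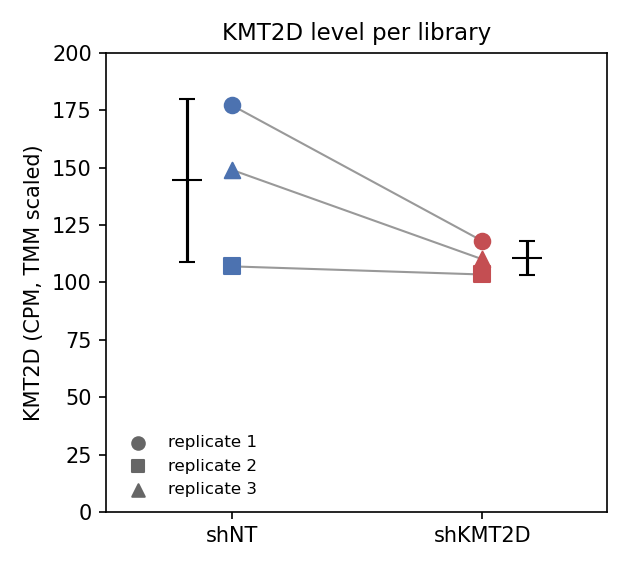
KMT2D level per library in TMM-scaled CPM, with grey lines joining libraries of equal replicate number and black bars showing group mean and SD (n = 3). The shKMT2D libraries lie between 103 and 118 CPM and the shNT libraries between 107 and 177 CPM.

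The libraries with replicate number 2 stood apart from the others in both groups. The first principal component of log2 CPM held 62.3% of the variance, with scores of 35.8 for shNT replicate 2 and 75.3 for shKMT2D replicate 2 and scores between -28.5 and -27.3 for the other libraries. Genes of DNA replication and the G1/S step were lower in replicate 2 than in the mean of replicates 1 and 3, by a median log2 difference of -1.16 in shNT and -1.82 in shKMT2D, over 52 genes. Mitosis genes differed by -0.89 and -1.92. Interferon-stimulated genes were higher in replicate 2, by 0.72 in shNT and 1.42 in shKMT2D, and genes of the integrated stress response by 1.47 and 0.29. The median difference was 0.44 in shNT and 1.19 in shKMT2D for the 7 tested fibroblast markers, 0.62 and 0.66 for the 6 leukocyte markers, and -0.12 and 0.11 for the 6 endothelial markers. MKI67, a marker of cycling cells, was at 211 CPM in shNT replicate 2 against 465 and 395 in shNT replicates 1 and 3, and at 90.6 in shKMT2D replicate 2 against 642 and 428. ASNS, which makes asparagine, was at 651 CPM in shNT replicate 2 and 201 in shKMT2D replicate 2, against 33.4 to 48.7 CPM in the other 4 libraries. MKI67 and ASNS were chosen after their values were seen. Replicate 2 was kept in the comparison, and the counts are also given without both of its libraries.

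**Figure D2:**
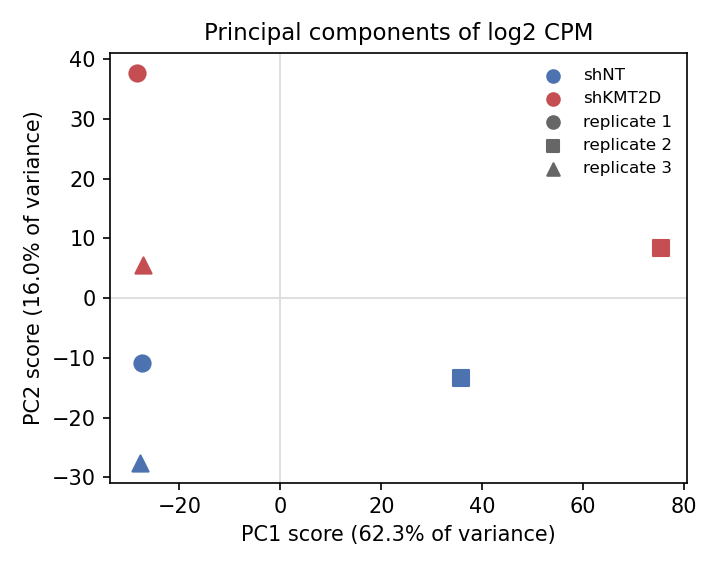
Scores of the 6 libraries on the first and second principal components of log2 CPM over 13590 genes, coloured by group and shaped by replicate number. Replicate 2 of shNT (35.8) and of shKMT2D (75.3) lie apart on the first component, on which the other 4 libraries lie between -28.5 and -27.3.

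No gene passed an adjusted p of 0.05 between shKMT2D and shNT with edgeR, with or without the replicate number as a block, although 266 genes had an unadjusted p under 0.05 without the block and 1158 with it. The smallest adjusted p was 0.494 without and 0.0898 with the block. limma-voom called 0 genes too. DESeq2 called 27 genes, 22 higher and 5 lower in shKMT2D, and with the block 116 genes, 91 higher and 25 lower, among which were all 27. Over all 13590 genes, the 3 libraries of each group did not overlap in 464 higher and 402 lower genes, 3.41% and 2.96%, where chance gives 5% each. Without both replicate-2 libraries, edgeR called 1 gene, VIM, and DESeq2 156, 69 higher and 87 lower. Without shKMT2D replicate 2 alone, DESeq2 called 26 higher and 26 lower, so the excess of higher genes was absent in both cases. On simulated counts, DESeq2 with the block gave 14 false calls among 185 where libraries of equal replicate number shared an effect and 71 among 211 where they did not. Without the block DESeq2 gave 0 false calls among 111 and 50 among 192. The simulated replicate effect was equal in both groups, whereas replicate 2 scored 35.8 in shNT and 75.3 in shKMT2D on the first principal component. The simulated false calls may therefore be too few for the real data. With the groups swapped within pair 2, DESeq2 with the block called 119 genes in the real data.

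Genes higher in shKMT2D by DESeq2 included several that were close to undetected in the control. VIM, vimentin, the intermediate filament protein of mesenchymal cells, rose from 0.674 ± 0.267 CPM in shNT to 9.17 ± 5.68 in shKMT2D (SD, n = 3 each; DESeq2 adjusted p = 9.7e-06). COL1A2, a chain of type I collagen, rose from 0.28 ± 0.119 to 4.55 ± 3.14 CPM (DESeq2 adjusted p = 3.9e-04). EDIL3, a secreted integrin-binding protein, PCDH7, a protocadherin, and TUB rose in the same way, from 0.134, 0.394 and 0.957 CPM to 2.85, 4.14 and 6.74. Of the 22 genes, 15 had a mean under 1 CPM in shNT, where 3 counts correspond to between 0.142 and 0.169 CPM, so their folds are imprecise. PRKAA2, a catalytic subunit of AMP-activated kinase, was at 0.0473 ± 0.0472 CPM in shNT and 1.1 ± 0.121 in shKMT2D. Better measured were LTB, lymphotoxin beta, which rose from 7.6 ± 0.934 to 27.1 ± 5.9 CPM (log2 fold change 1.84 ± 0.26 SE, DESeq2 adjusted p = 5.3e-08), and SOX4, a transcription factor, which rose from 48.7 ± 4.84 to 99.7 ± 19.3 CPM (log2 fold change 1.04 ± 0.23 SE, DESeq2 adjusted p = 0.0066). Other higher genes were SAMD5, LINC00221, LRP4, PTPN13, COL4A6, PLEKHG4B, LPAR1, GPC4, ZNF704, P3H3, CALML3, BATF and B4GALNT4.

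By DESeq2, 5 genes fell. PPP2R2C, a regulatory subunit of a serine/threonine phosphatase, fell from 17.2 ± 3.37 CPM to 5.26 ± 1.03 (log2 fold change -1.70 ± 0.29 SE, DESeq2 adjusted p = 8.7e-06). ATG12, needed to build the autophagosome, fell from 199 ± 23.6 to 121 ± 4.09 CPM, and CSF2RA, a receptor chain for the cytokine GM-CSF, from 42.5 ± 12.7 to 18.2 ± 3.85 CPM, with DESeq2 adjusted p of 0.033 and 0.045. SEMA6A, a semaphorin, and LRRC38 fell from 6.44 to 2.56 CPM and from 3.75 to 0.289 CPM. With the block DESeq2 further called H19, an imprinted noncoding RNA, and TIMP3, an inhibitor of matrix metalloproteinases, higher, from 27.7 ± 21.3 to 84.0 ± 61.6 CPM and from 80.8 ± 18.9 to 264 ± 191 CPM, and IL6 lower, from 94.9 ± 36.7 to 36.1 ± 15.9 CPM (SD, n = 3 each). All genes in these paragraphs were named after their values were seen, except VIM, COL1A2 and CALML3. The DESeq2 count without the block was 9 without shNT replicate 3, 11 without shKMT2D replicate 1, 16 without shNT replicate 1, 28 without shNT replicate 2, 33 without shKMT2D replicate 3 and 52 without shKMT2D replicate 2, with 9, 11, 13, 14, 21 and 21 of the 27 genes among them. Without shKMT2D replicate 2, edgeR's log2 fold changes of B4GALNT4, H19 and TIMP3 were 1.58, 0.82 and 0.95, each smaller by over 1.5 times than with it. With the block it was 29, 449 and 24 without the libraries of replicate 1, 2 and 3.

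**Figure D3:**
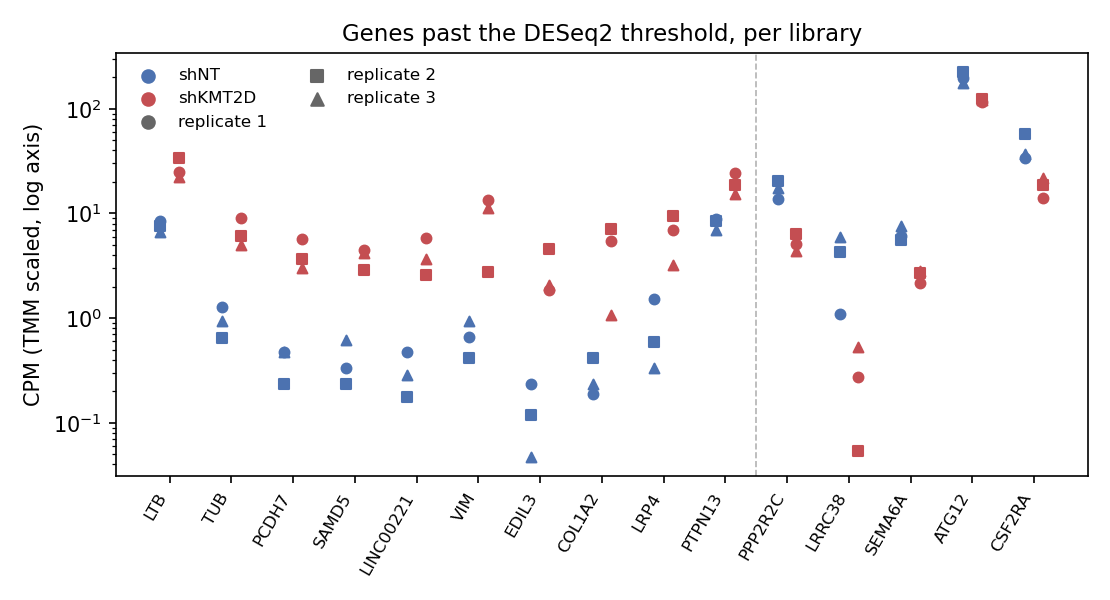
CPM per library on a log axis for the 10 higher genes of smallest DESeq2 adjusted p and, right of the dashed line, the 5 lower genes, coloured by group and shaped by replicate number. The 3 libraries of shNT and of shKMT2D do not overlap for any of the genes drawn, and VIM lies under 1 CPM in each shNT library. The genes were drawn because DESeq2 called them from these libraries, so their separation is no further support. Over all genes, 3.41% were higher and 2.96% lower without overlap, where chance gives 5% each.

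Of 38 tested mesenchymal genes, 2, VIM and COL1A2, rose when edgeR's p was adjusted over the list alone and 0 over all genes, and camera did not call the list (adjusted p = 0.187) except without shKMT2D replicate 1 (adjusted p = 0.0321). With the block, 3 members were higher and 2 lower when adjusted over the list alone. DESeq2 with the block called 3 of the 38 higher and 0 lower, more than the share among all tested genes (Fisher's exact test, one-sided, adjusted p = 0.0427 over 62 tests). That test takes genes as independent. camera with the block did not call the list (adjusted p = 0.086, and adjusted p = 0.802 with an estimated correlation), whose median log2 fold change was 0.18 and became -0.09 without both replicate-2 libraries. Of the 7 tested fibroblast markers, 1, COL1A2, rose when adjusted over the list alone, and this gene is shared with the mesenchymal list. COL1A1, the other type I collagen chain, had a log2 fold change of 0.48 ± 0.37 (SE) and a negative one without shKMT2D replicate 2. The fibroblast list did not pass camera (adjusted p = 0.187) except without shKMT2D replicate 3 (adjusted p = 0.00751).

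Type I interferon-stimulated genes were lower in shKMT2D as a list. Of 44 tested genes 40 had a negative fold change, with a median log2 fold change of -0.42, and camera with a preset correlation gave an adjusted p of 1.6e-11. With an estimated correlation, adjusted p = 0.85, so the call was lost. That test was not run on the simulated counts, so its power with 3 libraries per group is not known. No single member passed over all genes or adjusted over the list alone. With the block, 16 were lower when adjusted over the list alone and 22 had an unadjusted p under 0.05, and 24 of the 44 were lower in all 3 replicate pairs and 0 higher, against 16.7% and 16.0% of all genes. RSAD2 and MX1, both antiviral effectors, IFI6, and IRF7, a transcription factor of the interferon response, were the 4 members that DESeq2 with the block called, all lower, by -1.27 ± 0.25, -0.78 ± 0.18, -1.10 ± 0.25 and -0.91 ± 0.22 (log2 fold change ± SE). That share of its 25 lower genes was above the share among all tested genes (Fisher's exact test, one-sided, adjusted p = 7.1e-05 over 62 tests). Fisher's test takes genes as independent, whereas the estimated correlation within this list was 0.71, so its p is too small. With the block, camera with an estimated correlation (adjusted p = 0.802) and fry (0.741) did not call the list. MX1, IFI6 and IRF7 were named after their values were seen. Without single libraries, edgeR's log2 fold changes without the block ranged from -1.94 to -0.81 for RSAD2, -1.40 to -0.30 for MX1, -2.14 to -0.31 for IFI6 and -1.75 to -0.18 for IRF7, each lowest without shKMT2D replicate 2 and highest without shNT replicate 2 or, for IFI6, shKMT2D replicate 3. HERC6, a ubiquitin ligase family member, had the smallest edgeR p in the list and a log2 fold change of -0.65 ± 0.22 (SE). The list's median difference was -0.87, -0.15 and -0.42 in pairs 1, 2 and 3, and these genes were also higher in both replicate-2 libraries. The median was -0.71 without both replicate-2 libraries. It was -0.21 without shNT replicate 2, -0.23 without shKMT2D replicate 3, -0.998 without shKMT2D replicate 2 and -0.66 without shNT replicate 3, and camera with a preset correlation called the list in each case.

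Genes of cytokines and other NF-kappaB targets were lower as a list (35 tested, 25 with a negative fold change, median log2 fold change -0.21, camera adjusted p = 0.0019), which was lost with an estimated correlation (adjusted p = 0.85) and without shKMT2D replicate 1 (adjusted p = 0.523). The pair medians were -0.47, 0.10 and -0.13, so pair 2 went the other way. The median was -0.09 without shNT replicate 2, -0.14 without shKMT2D replicate 3, -0.36 without shKMT2D replicate 2 and -0.39 without both replicate-2 libraries. In the last case camera called the list with a preset correlation (adjusted p = 8.2e-06) and not with an estimated one (adjusted p = 0.874). Members moved both ways. PTGS2, the inducible cyclooxygenase, had a log2 fold change of 0.83 ± 0.20 (SE) and IL1RN, the interleukin 1 receptor antagonist, -2.98 ± 0.76 at under 1 CPM, and neither passed over all genes or adjusted over the list alone. DESeq2 with the block called 1 member higher, PTGS2, and 2 lower, IL6 and CXCL2. The lower share was above that among all tested genes (Fisher's exact test, one-sided, adjusted p = 0.0427 over 62 tests), a test that takes genes as independent. With the block, camera with an estimated correlation (adjusted p = 0.802) and fry (0.741) did not call the list. CXCL2 was named after its values were seen. Antigen presentation genes did not pass (20 tested, camera adjusted p = 0.339), with a median of 0.0043, a mean of -0.03 and a negative direction in the test. In that list TAP2, a peptide transporter, measured -0.31 ± 0.19 and CALR 0.25 ± 0.21 (log2 fold change ± SE). Without both replicate-2 libraries this list was called lower by camera with a preset correlation (median -0.32, adjusted p = 6.1e-06) and not with an estimated correlation (adjusted p = 0.874). It was also called with a preset correlation without shKMT2D replicate 2 (adjusted p = 1.4e-09) and without shNT replicate 3 (adjusted p = 0.00619).

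Keratinocyte differentiation genes were lower as a list: 25 of 33 tested members had a negative fold change, the median log2 fold change was -0.27 and camera gave an adjusted p of 5.3e-04. With an estimated correlation, adjusted p = 0.85. The call was also lost without shNT replicate 2 (median 0.02, adjusted p = 0.301) and without shKMT2D replicate 1 (adjusted p = 0.128). The median was -0.76 without shKMT2D replicate 2 and -0.51 without both replicate-2 libraries. In the latter case camera called the list with a preset correlation (adjusted p = 6.4e-05) and not with an estimated one (adjusted p = 0.874). The pair medians were -0.29, -0.03 and -0.42. SPRR1B, a cornified envelope precursor, measured -1.41 ± 0.49 at low counts, from 1.65 to 0.62 CPM. CALML3, a calmodulin-like protein of epithelium, rose by DESeq2 from 0.276 to 2.15 CPM. Basal keratinocyte genes did not pass as a list (32 tested, camera adjusted p = 0.726). PDPN, podoplanin, went from 12.96 ± 5.42 to 4.14 ± 1.57 CPM, a log2 fold change of -1.65 ± 0.43 (SE). FAT2, a cadherin of squamous epithelium, measured 0.94 ± 0.38. edgeR called neither over all genes, and DESeq2 with the block called PDPN lower and FAT2 higher (adjusted p = 4.5e-05 and 0.010).

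Among the cell cycle lists, mitosis genes were called lower (55 tested, 39 with a negative fold change, median log2 fold change -0.10, camera adjusted p = 0.0040, adjusted p = 0.85 with an estimated correlation), and G1/S genes were not called without the block (52 tested, median -0.05, adjusted p = 0.151) but were with it (adjusted p = 2.9e-04, median -0.53 in pair 2 and -0.0045 and 0.09 in pairs 1 and 3). With the block and an estimated correlation the G1/S call was lost (adjusted p = 0.802). Both lists were also lower in the replicate-2 libraries of both groups. The G1/S list was called lower without shNT replicate 2 (adjusted p = 2.5e-07), shKMT2D replicate 1 (6.3e-07) or shKMT2D replicate 3 (1.8e-04), and higher without shKMT2D replicate 2 (2.1e-08). The pair medians of the mitosis list were 0.05, -0.94 and 0.10, and without shKMT2D replicate 2 it was called in the other direction (median 0.31, camera adjusted p = 1.8e-09). The call was also lost without shNT replicate 1 (median 0.11, adjusted p = 0.696), without shNT replicate 3 (adjusted p = 0.133) and without both replicate-2 libraries (adjusted p = 0.269). CDK1, the mitotic kinase, measured -0.56 ± 0.49 and PTTG1, securin, -0.20 ± 0.18. CCNE1, cyclin E1, measured -0.42 ± 0.40 and RPA2 -0.20 ± 0.23 (log2 fold change ± SE).

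Integrated stress response genes also depended on a replicate-2 library, here that of shNT. The list was called lower (31 tested, 29 with a negative fold change, median log2 fold change -0.43, camera adjusted p = 3.1e-05, adjusted p = 0.85 with an estimated correlation), with pair medians of -0.06, -1.05 and 0.14. Without shNT replicate 2 it was called higher (median 0.28, adjusted p = 0.015), and without both replicate-2 libraries it was not called (median 0.05, adjusted p = 0.344). Without shNT replicate 1 or 3 the median was -0.65 or -0.68. CTH, an enzyme of cysteine synthesis, measured -1.84 ± 0.71 and STC2, stanniocalcin 2, -0.70 ± 0.31, and without shNT replicate 2 they measured -0.60 and -0.40. Cytosolic ribosomal proteins were called higher (76 tested, 73 with a positive fold change, median 0.19, camera adjusted p = 3.1e-05, adjusted p = 0.85 with an estimated correlation), with pair medians of 0.03, 0.37 and 0.06. The call was lost without shKMT2D replicate 2 (median -0.06, adjusted p = 0.263), without shNT replicate 1 (adjusted p = 0.129) and without both replicate-2 libraries (adjusted p = 0.0966). Without shNT replicate 2 or shKMT2D replicate 1 the median was 0.31 or 0.33. RPS29 measured 0.47 ± 0.31 (log2 fold change ± SE). Genes of ribosome biogenesis were not called without the block (43 tested, adjusted p = 0.187) and were lower with it (adjusted p = 0.044), with pair medians of 0.01, -0.35 and 0.11. With the block and an estimated correlation that call was lost (adjusted p = 0.802). This list too was called lower without shNT replicate 2 (adjusted p = 0.00811), shKMT2D replicate 1 (0.0039) or shKMT2D replicate 3 (4.1e-04), and higher without shKMT2D replicate 2 (0.0014). In that list NOP56 measured -0.43 ± 0.32 and PPAN -0.42 ± 0.40.

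The remaining lists called higher were those of Wnt, HOX and insulin signalling genes. In the Wnt list 22 of 30 tested genes had a positive fold change, with a median of 0.22 and a camera adjusted p of 3.1e-05, which became adjusted p = 0.85 with an estimated correlation and 0.0966 without both replicate-2 libraries. SFRP1, a secreted Wnt antagonist, measured 1.90 ± 0.49, from 1.765 to 6.62 CPM, and with the block DESeq2 called it. TCF7L1, a transcription factor of the pathway, measured 1.79 ± 0.46 at low counts, from 0.382 to 1.32 CPM. HOX genes, which specify position along the body axis, had a median of 0.17 (34 tested, 25 positive, camera adjusted p = 0.0030, adjusted p = 0.85 with an estimated correlation), lost without shNT replicate 2 (adjusted p = 0.0903), without shKMT2D replicate 2 (adjusted p = 0.512) and without both (adjusted p = 0.678). Its median was 0.27 without shKMT2D replicate 1 and 0.11 without shKMT2D replicate 2. HOXA13 measured 0.81 ± 0.33 and HOXA5 0.68 ± 0.33. Insulin and mTOR pathway genes had a median of 0.09 (27 tested, 20 positive, camera adjusted p = 0.029, adjusted p = 0.85 with an estimated correlation). That call was lost without any of shNT replicate 2 (adjusted p = 0.0903), shNT replicate 3 (0.158), shKMT2D replicate 1 (0.214) or shKMT2D replicate 2 (0.109). Without both replicate-2 libraries the list was called (median 0.16, adjusted p = 0.0173), but not with an estimated correlation (adjusted p = 0.874). Its median was 0.04 without shKMT2D replicate 1. IGFBP3, which binds insulin-like growth factors, measured 0.98 ± 0.41 and IRS2, an insulin receptor substrate, 0.52 ± 0.25, and without shKMT2D replicate 2 they measured 0.37 and 0.26. DESeq2 with the block called IGFBP3 higher. Over all 31 lists tested, camera called 9, 4 higher and 5 lower, with the block 11, and without both replicate-2 libraries 7. With an estimated correlation it called 0, with or without the block and without both replicate-2 libraries. Calls given without single libraries used the preset correlation, and an estimated one was not run for them.

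**Figure D4:**
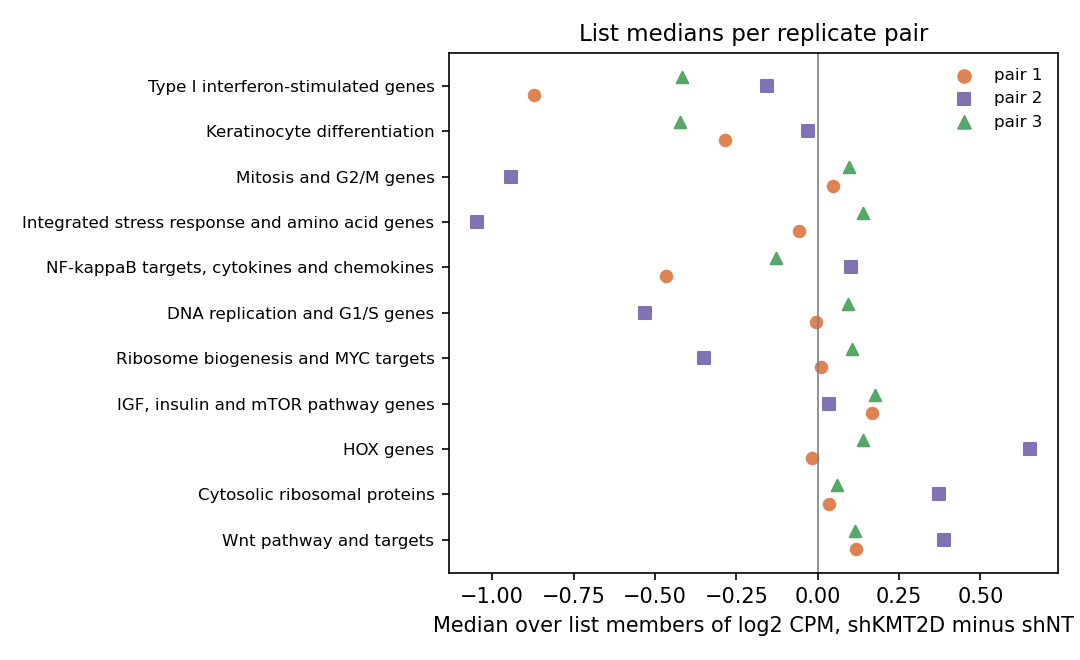
Median over each list's members of the log2 CPM difference, shKMT2D minus shNT, within each replicate pair, for the 11 lists that camera called with the replicate block. The interferon list is negative in each pair (-0.87, -0.15 and -0.42), whereas the mitosis list is at -0.94 in pair 2 and at 0.05 and 0.10 in pairs 1 and 3.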

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

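The alternatives with DESeq2 or limma-voom and the block, with pairs 1 and 3 only, with library weights, and DESeq2 without each library were chosen after seeing the data. The KMT2D log2 fold change stayed negative and short of the threshold in every alternative run, between -0.52 and -0.35, and between -0.56 and -0.21 without single libraries, with adjusted p from 0.0585 (DESeq2, pairs 1 and 3) to 1.00. edgeR's count of 0 genes held for RLE factors, library sizes alone, upper-quartile factors, both filters, glmTreat, an adjusted p below 0.01, the replicate block and each left-out library, and for limma-voom with and without the block. The count was 27 with DESeq2 (22 higher, 5 lower), 116 with DESeq2 and the replicate block (91 higher, 25 lower), 1 with pairs 1 and 3 only (1 higher), 156 with DESeq2 on pairs 1 and 3 (69 higher, 87 lower) and 13 with library weights in limma-voom (11 higher, 2 lower), and the cause of these differences was not tested. DESeq2 called 3 lower genes with no filter. Without single libraries its count ranged from 9 to 52 (8 to 29 higher, 1 to 26 lower). With the replicate block and 1 pair left out, it ranged from 24 to 449 (18 to 188 higher, 5 to 261 lower).

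The number of lists called was 0 with an estimated correlation, 0 with fry and 0 for both with the replicate block, and 8 to 14 without single libraries, the highest without shKMT2D replicate 3. Adding the replicate block to camera added the G1/S and ribosome biogenesis lists and changed no other call of a list by camera or of a gene over all genes by edgeR. fry's mixed test called 0 lists without the block and 2 with it, keratinocyte differentiation (adjusted p = 0.0097) and leukocyte markers (0.026). The interferon median was -0.42 (adjusted p = 0.85) with an estimated correlation and -0.42 (adjusted p = 0.933) with fry, and with the replicate block -0.48 for both (adjusted p = 0.802 and 0.741), and ranged from -0.998 to -0.21 without single libraries. Those tests allow for genes of a list varying together between libraries. Their power was not measured, so a call lost with them does not show that a list was unchanged. The mitosis median was 0.069 on pairs 1 and 3 only and -0.40 to 0.31 without single libraries, that of the integrated stress response 0.050 and -0.68 to 0.28, that of ribosomal proteins -0.062 to 0.33 and that of keratinocyte differentiation -0.76 to 0.016 without single libraries. Each of these medians changed sign without 1 of the replicate-2 libraries, and that of mitosis also without shNT replicate 1. The cause was not tested. Of the named genes, none of which passed in edgeR, ADM was at -0.22, -0.21 and -0.063 on pairs 1 and 3, with DESeq2 on these, and with library weights (-0.068 to 1.07 without single libraries), PFKFB3 at -0.11, -0.10 and -0.10 (-0.0067 to 0.42) and DLL1 at -0.024 on pairs 1 and 3 with edgeR and -0.021 with DESeq2 (-0.19 to 1.42), while COL1A1 ranged from -0.036 to 0.70 without single libraries. MKI67, at 0.12 with edgeR, was at -0.20 with the replicate block, -0.19 with DESeq2 and the block, -0.21 with limma-voom and -0.31 with limma-voom and the block (-0.46 to 0.58 without single libraries), and ASNS, at -1.35, was at 0.058 on pairs 1 and 3 and 0.061 with DESeq2 on these (-2.51 to 1.22). The other named-gene values kept their sign in each alternative, and 108 passed a threshold that the edgeR value did not, as calls of another test or subset of libraries. Of 90 named genes besides KMT2D, 40 moved by over 1.5 times or changed sign without at least 1 library, most often without shKMT2D replicate 2 (28 genes) or shNT replicate 2 (18 genes). Another scaling moved the median of all genes by -0.021 to 0.018, and with library sizes alone the medians near 0 of other chromatin regulators, antigen presentation, AP-1 and cholesterol genes turned negative (-0.0077, -0.030, -0.019 and -0.015), without a call. With the filter on CPM the median of endoplasmic reticulum chaperones turned positive (0.0040). Depth limits the genes under 1 CPM, where 3 counts correspond to 0.142 to 0.169 CPM.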

Other observations

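Chosen only after the results were seen were the fits without both replicate-2 libraries, DESeq2 with the block, the tests of other cell types and of a fixed admixture, and the splits of the libraries.

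HBEGF, a ligand of the EGF receptor, fell from 318 ± 112 to 169 ± 66.2 CPM (SD, n = 3 each; DESeq2 adjusted p = 1.8e-04 with the block, edgeR adjusted p = 1.00), and AREG, another such ligand, had a log2 fold change of -0.73 ± 0.32 (SE). Their list of AP-1 and immediate early genes (36 tested) had a median of 0.0029, a mean of 0.16 and a negative direction in camera (adjusted p = 0.219), and it was called higher without shKMT2D replicate 1 (adjusted p = 0.043) and lower without shKMT2D replicate 2 (8.5e-06) or both replicate-2 libraries (3.4e-04), the last not with an estimated correlation (adjusted p = 0.874). Other calls without single libraries in this part used the preset correlation. FADS2, a fatty acid desaturase, measured 0.46 ± 0.29. The cholesterol list (30 tested, adjusted p = 0.664) was called lower without shKMT2D replicate 3 (7.0e-04) and higher without shNT replicate 3 (1.6e-05) or shKMT2D replicate 2 (0.0058). FST, the activin antagonist follistatin, measured 0.80 ± 0.22 and INHBA, an activin subunit, -0.52 ± 0.28, in a TGF-beta list (29 tested, adjusted p = 0.237) called higher without shKMT2D replicate 3 (0.041).

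The other lists did not pass camera, and no member passed edgeR over all genes. Epithelial junction genes (35 tested, adjusted p = 0.726) had a median of -0.01 and a mean of 0.02, with CLDN1, a tight junction protein, at 0.55 ± 0.19 and CGN, cingulin, at -0.31 ± 0.16 (log2 fold change ± SE, here and below). Glycolysis genes (25 tested, adjusted p = 0.981) were called higher without shKMT2D replicate 2 (0.029) and without both replicate-2 libraries (0.0078, but adjusted p = 0.874 with an estimated correlation), with PFKFB3 at 0.27 ± 0.25 and ENO2 at 0.18 ± 0.22. Hypoxia genes (28 tested, adjusted p = 0.464) included BHLHE41 at 0.86 ± 0.45 and ADM at 0.74 ± 0.49. Oxidative phosphorylation genes (56 tested, adjusted p = 0.225) were called lower without shNT replicate 1 (0.047), with NDUFB6 at -0.41 ± 0.16 and UQCRQ at -0.51 ± 0.21. Among p53 targets (37 tested, adjusted p = 0.569), RPS27L measured -0.36 ± 0.14 and FAS -0.38 ± 0.23. Endoplasmic reticulum chaperones (22 tested, adjusted p = 0.981) had a median of -0.0014 and a mean of 0.01, with ERN1 at -0.37 ± 0.22 and SEC61B at -0.28 ± 0.19. NRF2 targets (27 tested, adjusted p = 0.787) included ABCC2 at 0.76 ± 0.43 and AKR1B1 at -0.62 ± 0.35. Notch genes (22 tested, adjusted p = 0.406) were called higher without shKMT2D replicate 1 (0.038), with DLL3 at 0.70 ± 0.37 and DLL1 at 1.03 ± 0.65. Canonical histone genes (14 tested, adjusted p = 0.187) were called higher without shKMT2D replicate 1 (0.038) or shNT replicate 3 (0.042), with HIST1H2AG at 0.76 ± 0.40 and HIST1H2AE at 0.65 ± 0.51, and both share sequence with other histone genes. Endothelial markers (6 tested, adjusted p = 0.339) included ROBO4 at -0.60 ± 0.37 (-0.19 without shNT replicate 2) and ENG at -0.13 ± 0.14. Leukocyte markers (6 tested, adjusted p = 0.785) had a median of 0.07 and a mean of -0.06, with LCP1 at 0.57 ± 0.23 and CORO1A at -0.54 ± 0.23. The 4 tested melanocyte and neuroendocrine markers were higher in each of the 3 pairs and were too few for a list test.

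The lower level of interferon-stimulated genes in shKMT2D (median -0.42) was not produced by the replicate-2 libraries alone, since the median was -0.71 without them. It was not produced by GC content or transcript length either: with each library's trend removed, the median over the pairs went from -0.48 to -0.47, and camera with the block and a preset correlation still called the list (adjusted p = 3.9e-18), a call that without this removal was lost with an estimated correlation (adjusted p = 0.802) and with fry (0.741). Of the 10 splits of the 6 libraries, 9, the real one included, called at least as many lists as the real one (9, highest other 16). Of the 4 splits that part all 3 pairs, all 4 did with the block (11, highest other 18). These are too few for a share under 0.05, and they count all lists, so they do not test the interferon list itself. They show that camera with a preset correlation called as many lists for other groupings of these libraries. An effect of the knockdown, a hairpin effect on other transcripts, variation of interferon activity between cultures and a chance difference between the libraries stay open. The hairpin of each library is not stated. The pair differences of KMT2D (-0.59, -0.05 and -0.44) and of this list (-0.87, -0.15 and -0.42) are given as values only.

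The replicate-2 libraries of both groups stood apart with low cell cycle genes, which GC content and transcript length did not produce, as the G1/S median of replicate 2 minus the others was still -1.2 in shNT with each library's trend removed. Of 8 markers of fibroblasts, endothelial cells or leukocytes, given like all CPM in this paragraph without TMM scaling, DCN, LUM and PTPRC had 0 counts in every library, and the highest in replicate 2 was CDH5 at 3.78 CPM, against 3.73 to 6.61 in replicates 1 and 3, a baseline that would hide a small share, followed by PECAM1 at 0.409 in shKMT2D, against 0 to 0.0536 in replicates 1 and 3. In the other direction, the medians of the fibroblast list (0.44 in shNT and 1.19 in shKMT2D) and of the leukocyte list (0.62 and 0.66) were higher in replicate 2, PDGFRB was at 2.09 and 3.07 CPM there against 0.589 to 1.18 in the other libraries, and COL1A1 was at 24.0 CPM in shKMT2D replicate 2 against 9.40 to 12.53 in the other libraries. The 0 counts argue against a large share of fibroblasts or leukocytes and PECAM1 against one of endothelial cells, while a small share and a culture, collection or library difference stay open, and no biological explanation was tested.

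The 15 genes under 1 CPM in shNT that DESeq2 called higher, VIM and COL1A2 among them, could come from cells of another kind in the shKMT2D libraries. SPARC, COL3A1, DCN, LUM and THY1 together changed by -0.0187 of the rise of VIM, in CPM without TMM scaling. These 5 were chosen after the results were seen, and they argue only against mesenchymal cells rich in them. Other mesenchymal cells stay open, since COL1A2 rose from 0.28 to 4.55 TMM-scaled CPM. Of 38 tested mesenchymal genes, 23 had a positive and 15 a negative fold change. The spread of the 15 genes beyond a common ratio across the shKMT2D libraries was 13.6 (chi-square per degree of freedom). That exceeds counting error, so it argues against a source whose transcripts keep a fixed ratio in all shKMT2D libraries. The spread lay at percentile 46.3 of 1000 random sets of equally abundant genes, whose median was 14.1. A source whose transcripts vary between libraries as those genes do cannot be told apart from a change within the cells. The bound of this measure was reset after a first bound did not separate the outcomes. Of the 10 splits, 4 gave at least 27 DESeq2 genes (highest other 276, which sets shNT replicates 1 and 3 and shKMT2D replicate 3 against the rest and points to a structure of the samples). For edgeR's 0 genes such a count is 10 of 10 by construction and tests nothing (highest other 0). With the block, 2 of the 4 splits that part all pairs gave at least 116 genes, the other being the swap of pair 2 with 119, and neither number of splits allows a share under 0.05.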
